A study of Mus musculus with 4 samples.

How the data were processed

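The deposited matrices hold UMI counts per gene and cell barcode, which the authors made with Cell Ranger 6.1.2 and the mm10 genome from 10x Genomics 3' libraries, per the labels. No normalization had been applied to these counts: the values were whole numbers and every barcode had at least 500 UMIs. The 4 libraries come from 4 mice, 2 per genotype, and the labels give no sequencing batch, date or litter. The matrices list 32285 gene IDs, of which 32158 were found by ID in the GENCODE M21 annotation (GRCm38, mm10), the source of gene positions. Counts of different libraries differed by far more than sampling noise (chi-square per degree of freedom from 44.0 to 130), so no library was a copy of another.

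The cell filters, the gene lists, the marker lists, the tests and the rule for named genes were chosen before the data were examined. A barcode was kept with at least 300 genes, at least 500 UMIs and at most 20% of UMIs from mitochondrially encoded genes, which left out 16.2% and 13.9% of barcodes in the PSp mice and 14.0% and 11.3% in the PCSp mice by the last limit. Doublets were scored with Scrublet as in scanpy 1.11.5. Its automatic threshold marked 0.110%, 0.387%, 1.07% and 1.25% of barcodes, so the highest-scoring barcodes were left out instead, 0.8% per 1000 barcodes of the library (237, 308, 545 and 572). Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen within libraries, and 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1 gave the clusters, with no batch correction (Python 3.11.15, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9). A cluster took the name of the class whose markers scored highest, within the limits that follow. At least 3 of these markers had to have a log2 fold of 1 or more over the median of the cluster means. They also had to be seen in at least 10% of its cells. Its 10 leading genes had to point to no other class. A cluster of low UMI count also took no name if none of these leading genes was a marker of the class. Epithelial-like cells were clustered again in the same way and named basal, luminal, luminal progenitor or neuroendocrine. Classes and subclasses are named after their markers alone, and genes used as markers are not reported as results of the clustering.

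For each class with at least 50 cells in every mouse, counts were summed per mouse and tested with the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3, TMM normalization, filterByExpr, genotype as the term), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. All tests were two-sided, and the standard error of a log2 fold change was taken from its F statistic. The common dispersion in the epithelium gave a biological coefficient of variation of 15.6%, with 2 residual degrees of freedom and 3.06 prior degrees of freedom. The 32 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, for lists with at least 5 genes tested and with adjustment over the lists, and with an estimated correlation and fry beside it. Fry tests whether the genes of a list move, on balance, one way. Counts adjusted over the list alone use the edgeR p values of its genes. The lists include cholesterol biosynthesis, SREBP2 control and cholesterol uptake, fatty acid synthesis, cholesterol efflux and storage, steroid hormone synthesis, luminal progenitor, basal and neuroendocrine markers, lineage factors of CHD1 loss studies, SPOP substrates, the cell cycle, homologous recombination, p53 and senescence, the mesenchymal transition, the interferon response, MHC class I and class II, NF-kB, myeloid-recruiting cytokines, hypoxia and glycolysis, oxidative phosphorylation, the unfolded protein and stress response, PI3K feedback, dissociation stress, secretory transcripts, mitochondrially encoded genes, 2 macrophage states, T and NK cell cytotoxicity, T cell exhaustion, and fibroblast activation and matrix.

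Shares of classes were tested with edgeR on the numbers of cells without a trend and with the exact permutation test of the 4 mice, whose smallest p is 0.333. The share of a single mouse is given with its exact Clopper-Pearson 95% interval. The RNA that one class could leave in another was taken as the level of a gene in the first, times the highest ratio between the classes of the 3 most abundant markers of the first; the class that could leave most is the one given. The difference of the genotype effect between classes was tested in edgeR on the sums of both classes with mouse, class and the interaction of class and genotype as terms.

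The genes named in the epithelium are Chd1, Spop and Srebf2, then the 10 of largest and the 10 of smallest log2 fold change among those that passed with a mean of at least 20 CPM and both PCSp mice on one side of both PSp mice, and from each list the 3 genes of smallest p. Since none passed, each direction was filled to 5 by the smallest p, and these are said not to pass. List members are given for the 10 lists that passed, for the lists of cholesterol biosynthesis and SREBP2 control, and where a gene passed over its list alone; Wfdc2, in 2 lists, is given once. In each other class and subclass up to 5 genes per direction were named by the same criteria without filling up. Predicted gene models were counted and not named. Some genes and 1 list that meet these criteria are left out of the text, with their results. Any other gene is said to have been chosen after its values were seen, or is named for a test of its difference between classes.

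The tests were checked on simulated counts of the same depth and number of mice, with 200 genes changed by 0.5, 1 or 2 on the log2 scale and 1 list moved. With the spread of the fitted trend, 3.64% of the epithelial calls were false over 16204 genes, and the other classes had from 1.42% in T and NK cells (7575 genes) to 7.33% in macrophages and monocytes (9829 genes). With the spread that edgeR fitted to each gene, false calls reached 13.3% in the epithelium (16163 genes) and 15.6% in neutrophils (8889 genes), above the nominal level. Genes were simulated independently of each other, and lists were tested at the preset correlation only. The moved list was called in the epithelium with either spread. Without a change, 2 of 32 epithelial lists were called with the spread of each gene and 0 of 31 with that of the trend. Of genes changed by 1, edgeR found 67 of 67 in the epithelium and 38 of 67 in endothelial cells (8896 genes), and of genes changed by 0.5 it found 26 of 67 and 2 of 67; all 66 genes changed by 2 were found in both.

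Alternatives tried were DESeq2 1.42.0 in place of edgeR, its size factors in place of TMM, no filter on low counts, each mouse left out in turn, doublets kept, a stricter cell filter (at least 1000 genes and at most 10% mitochondrial UMIs), all barcodes, Leiden resolutions of 0.5 and 2, naming of cells by their own markers, luminal-like cells only, all cells summed, and equal cells and depth per mouse (2745 cells and 35849452 UMIs). Alternatives added after the data were seen were the same number of cells from each epithelial sub-cluster in every mouse (2125 cells per mouse), leaving out sub-clusters of low UMI count or led by immune genes (7815 cells left), leaving out neuroendocrine-like cells, leaving out the sub-cluster led by uroplakin genes from the luminal-like cells, the same number of cells from each cluster in the other classes, and the tests of lists in subclasses and other classes under these settings. B and plasma, smooth muscle and glial cells were too few for a gene test and enter the shares alone.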

Results

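Single-cell RNA profiles were taken from 4 whole prostate tumours, 1 per mouse, with a 3' tag method that counts each captured transcript as a unique molecular identifier (UMI). Levels of genes are given as CPM, the UMI count scaled to the library total. The mice of both genotypes carry, among other alleles, a prostate epithelial Cre and a mutant form of SPOP, the substrate adaptor of a ubiquitin ligase that is often mutated in prostate cancer. In the 2 PCSp mice the chromatin remodeller gene Chd1 is floxed as well, and the 2 PSp mice keep it. All mice were castrated at 9 months of age and their tumours were collected 1 month later. The libraries held 6539 and 7266 barcodes in the PSp mice and 9656 and 9600 in the PCSp mice, with totals of 75339204, 86435756, 90839725 and 66874620 UMIs. Median UMIs per barcode were 3606 and 3757 in the PSp mice and 3448.5 and 2289 in the PCSp mice, with median numbers of genes of 1345, 1364, 1352 and 1004. After the cell filters 5211, 5900, 7708 and 7883 cells were left. By their markers 12661 of these were epithelial-like. Among the epithelial-like cells, 4742 lay in 5 sub-clusters with a median under 3000 UMIs. The largest of these 5, sub-cluster 2 (2201 cells, median 1247 UMIs), took no subclass name and was led by Igkc and Apod. Whether such barcodes hold whole epithelial cells was not tested. The lower depth of PCSp mouse 2 was also seen in the epithelial-like cells, whose median UMIs were 11066 and 14047.5 in the PSp mice and 9740.5 and 8145.5 in the PCSp mice.

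The shares of cell classes address whether loss of Chd1 went with another cellular makeup of the castrated tumour. Epithelial-like cells made up 51.7% ± 1.44 (SD, n = 2) of the cells in PSp tumours and 44.5% ± 2.77 (SD, n = 2) in PCSp tumours. Macrophages and monocytes, the phagocytes of the tumour, made up 7.08% ± 0.0281 (SD, n = 2) and 8.88% ± 0.195 (SD, n = 2). Neutrophils, the most common immune cells here, made up 21.2% ± 2.90 and 22.8% ± 7.33, and fibroblasts 10.8% ± 0.961 and 13.3% ± 2.36. T and natural killer (NK) cells made up 3.67% and 4.56%, and endothelial cells 2.92% and 3.04%. Rarer were B and plasma cells with 0.533% and 0.858%, smooth muscle cells and pericytes 0.779% and 0.861%, and glial cells 0.414% and 0.251%. Cells of clusters that took no name made up 0.892% and 0.983%.

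No class passed the test of its share. The edgeR count model called 0 of 10 shares, with 0 at an unadjusted p under 0.05. The exact two-sided permutation test of 2 against 2 mice cannot give a p under 0.333. The epithelial log2 ratio was -0.22 ± 0.15 (SE, edgeR adjusted p = 0.372, exact permutation p = 0.333), and that of macrophages and monocytes was 0.33 ± 0.14 (edgeR adjusted p = 0.372, exact permutation p = 0.333). Both PCSp mice lay below both PSp mice for epithelial cells. The 4 shares were 52.7% (exact Clopper-Pearson 95% interval 51.3 to 54.0), 50.6% (49.4 to 51.9), 46.4% (45.3 to 47.5) and 42.5% (41.4 to 43.6). These intervals cover counting error only, not the difference between mice or losses in dissociation. The neutrophil ratio of 0.10 turned to -0.03 without PSp mouse 1 and to -0.27 without PCSp mouse 2, and the endothelial ratio of 0.06 turned to -0.30 without PCSp mouse 1. The epithelial ratio was -0.06 at Leiden resolution 2 and -0.11 with the stricter cell filter. At resolution 2, clusters that took no name held 1164 and 1284 cells in PSp mice and 1482 and 1304 in PCSp mice. The ratio of macrophages and monocytes was 0.69 with the stricter filter (unadjusted p = 0.0358, adjusted p = 0.139) and 0.13 as a share of non-epithelial cells. The neutrophil ratio was -1.07 with the stricter filter and the endothelial ratio 0.35 without PCSp mouse 2, and no share passed in any setting. The stricter filter took neutrophils from 2209 to 180 in PCSp mouse 2, whose library had the lowest depth. In PCSp mouse 1 they went from 1361 to 545, and in the PSp mice from 1000 to 506 and from 1374 to 632. Shares under that filter therefore rest on unequal losses between the libraries.

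**Figure D1:**
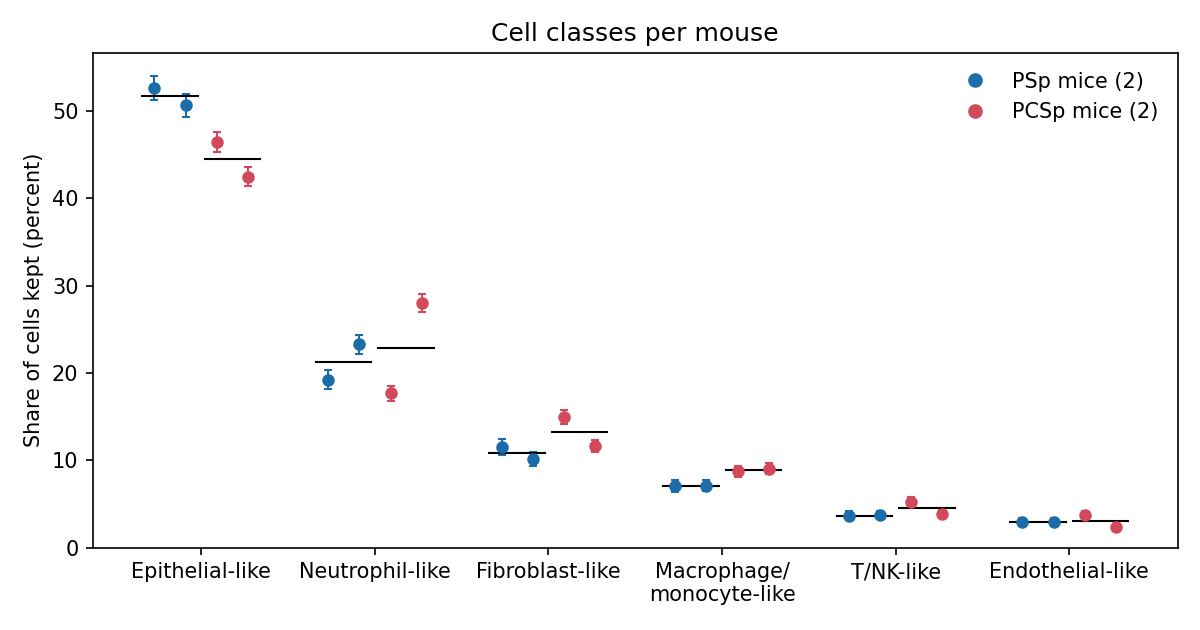
Each point is the share of all cells kept (percent, y axis) that fell in a cell class (x axis) in 1 mouse, with its exact 95% binomial interval; black lines are the means of the 2 PSp and the 2 PCSp mice. The epithelial-like shares of the PCSp mice, 46.4% and 42.5%, lie below those of the PSp mice, 52.7% and 50.6%.

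Within the epithelium, basal-like cells, which carry the keratins Krt5 and Krt14, made up 27.9% ± 8.19 (SD, n = 2) of epithelial-like cells in PSp tumours and 31.9% ± 4.30 in PCSp tumours. Luminal-like cells made up 6.23% ± 5.67 and 4.53% ± 2.44, luminal-progenitor-like cells 9.31% ± 7.76 and 8.02% ± 0.995, and neuroendocrine-like cells 0.295% ± 0.0563 and 0.501% ± 0.201. The luminal-progenitor-like cells include sub-cluster 7, in which the uroplakin genes Upk1a and Upk2 lead beside Psca, the only marker of the subclass among its 10 leading genes. It held 0.874% and 1.37% of epithelial-like cells in PSp mice and 2.29% and 1.01% in PCSp mice, so its identity as a luminal progenitor is open. The larger luminal-progenitor-like sub-cluster 10 (923 cells) met 5 of 10 markers. Its first leading gene was the uroplakin gene Upk1b, and none of its 10 leading genes was a marker of the subclass. Its identity is open as well. Cells of sub-clusters that took no subclass name made up 56.2% and 55.0%. Among them, sub-cluster 4 (1375 cells) met 4 of 10 luminal progenitor markers. It took no name because Ltf, which is on the neutrophil marker list, was among its leading genes. The luminal-like and luminal-progenitor-like shares and sums therefore leave it out. No share of a subclass passed (edgeR adjusted p = 0.915 for each, 0 of 5 at an unadjusted p under 0.05), and the spread between the PSp mice was large: luminal-like shares were 2.22% and 10.2% and luminal-progenitor-like shares 3.83% and 14.8%. Without PSp mouse 2 the log2 ratios of basal-like, luminal-like and luminal-progenitor-like cells turned from 0.19, -0.46 and -0.22 to -0.08, 1.03 and 1.07, and the luminal-like ratio was 0.01 without PCSp mouse 2. The basal-like ratio was -0.12 at Leiden resolution 2, where the luminal-like ratio was -0.85 and the luminal-progenitor-like ratio -0.06.

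The comparison of epithelial-like cells asks which genes differ where the Cre acts. Chd1 itself (ENSMUSG00000023852, chromosome 17, 15704967 to 15772610, plus strand, GRCm38) was at 90.8 and 79.7 CPM in the PSp mice and at 59.2 and 56.5 in the PCSp mice, a log2 fold change of -0.56 ± 0.09 (SE, edgeR adjusted p = 0.405 over all genes). In luminal-like cells alone the fall was smaller, from 79.9 and 79.6 to 65.3 and 65.0 CPM (-0.29 ± 0.09 SE, adjusted p = 0.347), and in basal-like cells it was -0.54 ± 0.11 (SE, adjusted p = 0.132). A 3' tag can lie outside the deleted part of a floxed gene, and it then does not check the deletion, so transcripts left in PCSp mice do not show intact protein. In the other classes the Chd1 log2 fold change was 0.27 in fibroblasts, 0.28 in neutrophils, 0.44 in macrophages and monocytes, 0.47 in T and NK cells and 0.19 in endothelial cells, with no adjusted p under 0.189. The fold change in epithelial cells was lower than that in T and NK cells by a test of the difference (-1.01 ± 0.17 SE, adjusted p = 3.1e-06) and lower than that in neutrophils (-0.83 ± 0.16 SE, adjusted p = 0.0462). Spop was at 0.12 ± 0.08 (SE, edgeR adjusted p = 0.738) and Srebf2, which encodes the master regulator of cholesterol synthesis SREBP2, at -0.01 ± 0.12 (SE, edgeR adjusted p = 0.994).

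**Figure D2:**
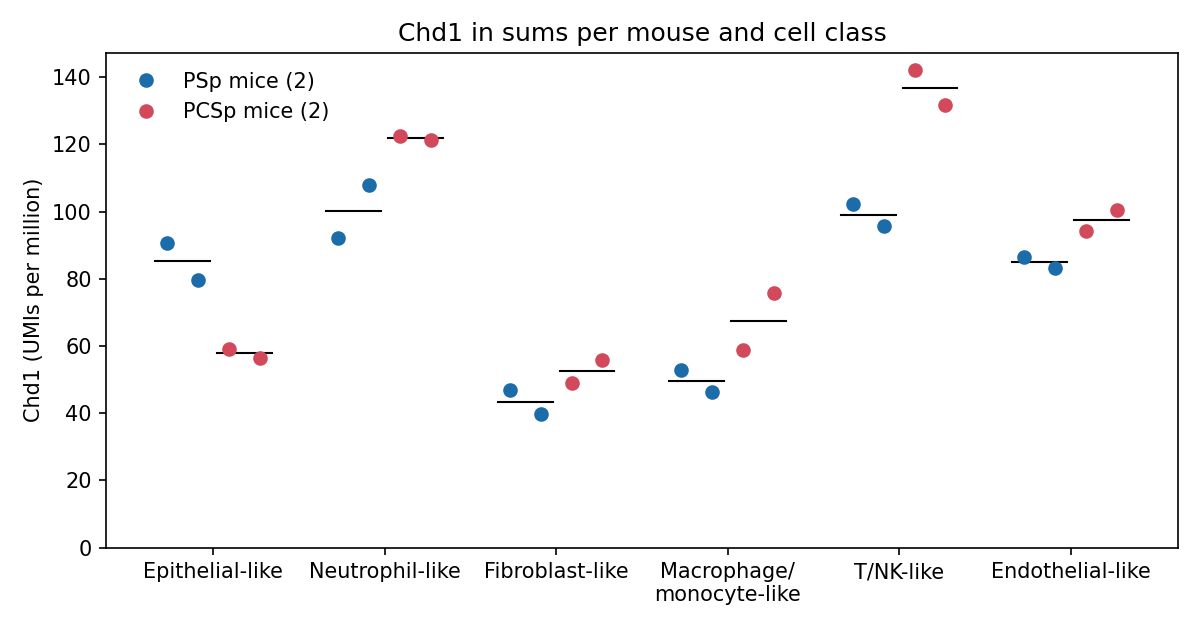
Each point is the Chd1 level (CPM, y axis) in the summed cells of 1 class (x axis) from 1 mouse, and black lines are the means of the 2 PSp and the 2 PCSp mice. In epithelial-like cells the PCSp mice lie at 59.2 and 56.5 and the PSp mice at 90.8 and 79.7, while in T and NK-like cells the PCSp mice lie above the PSp mice.

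No epithelial gene passed the edgeR test: 0 of 16451 genes, with 1266 at an unadjusted p under 0.05, of which 670 were higher in PCSp mice and 596 lower. DESeq2 called 181 genes on the same sums, 76 higher and 105 lower. The genes of smallest p that were higher, none of which passed, were Wdfy1 (log2 fold change 1.46 ± 0.10 SE, adjusted p = 0.261), which encodes an endosomal adaptor of Toll-like receptors, and Ccdc148 (0.90 ± 0.09). Next came the haptoglobin gene Hp (0.75 ± 0.08), Wdr89 (0.65 ± 0.08) and Tbpl1 (0.61 ± 0.08), which encodes a relative of the TATA-binding protein. Those that were lower, again without passing (adjusted p = 0.405 each), were Trim12a (-1.42 ± 0.14), of the family of antiviral TRIM proteins, Fam32a (-0.69 ± 0.07) and the tissue kallikrein gene Klk1 (-2.64 ± 0.30). They also included the interferon-induced Oas2 (-0.82 ± 0.11) and Slfn2 (-0.71 ± 0.09). On simulated data of the same depth with 16204 genes, edgeR found 26 of 67 genes changed by 0.5 on the log2 scale (38.8%), 67 of 67 changed by 1 and 66 of 66 changed by 2. Of 165 calls 6 were false. When the simulated spread was the one fitted to each gene, edgeR found 19, 65 and 66 of these, and 23 of 173 calls were false (13.3%). Sizes between 0.5 and 1 were not simulated, and real changes of 1.42, 1.46 and 2.64 did not pass although nearly all simulated ones of 1 and all of 2 were found. The edgeR count was 29 with no filter on low counts, 2 without PSp mouse 1 and 2 without PSp mouse 2.

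At the preset correlation between genes, camera called 10 of the 32 fixed lists in the epithelium, most of them downward. The interferon response genes, which cells switch on against viruses, fell in PCSp mice, with a mean log2 fold change of -0.71. All 22 were lower, 18 with p values adjusted over the list alone against 0 over all genes (camera adjusted p = 9.3e-43 over 32 lists; adjusted p = 0.748 with an estimated correlation). Among them Usp18, which restrains interferon signalling, was at -0.78 ± 0.10, Ifi44 at -0.96 ± 0.15 and Bst2, which tethers budding viruses to the membrane, at -0.80 ± 0.14 (SE). The genes of MHC class I presentation, which show peptides to T cells, fell with a mean of -0.44. All 11 were lower, 1 of them when adjusted over the list alone (adjusted p = 1.0e-09; adjusted p = 0.777 with an estimated correlation). Here the peptide transporter gene Tap1 was at -0.62 ± 0.12, the light chain gene B2m at -0.62 ± 0.20 and the class I transactivator gene Nlrc5 at -0.67 ± 0.21. Without PCSp mouse 2 the mean was -0.27, B2m was -0.37 and Nlrc5 -0.43, and without PCSp mouse 1 the mean was -0.64 and B2m was -0.93. Genes of hypoxia and glycolysis fell with a mean of -0.26. Of these, 18 of 20 were lower, 13 when adjusted over the list alone (adjusted p = 1.2e-09; adjusted p = 0.627 with an estimated correlation). Bnip3, which acts in the removal of mitochondria, was at -0.36, and the glycolytic enzyme genes Eno1 and Pgam1 were at -0.35 and -0.33.

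Genes of the cell cycle fell with a mean of -0.34, all 25 lower and 0 when adjusted over the list alone (adjusted p = 8.6e-09; adjusted p = 0.777 with an estimated correlation). The mitotic kinase gene Cdk1 was at -0.60 ± 0.12, Ube2c at -0.43 ± 0.12 and the proliferation marker Mki67 at -0.48 ± 0.13. The mean was -0.22 without PSp mouse 1. The sub-cluster of cycling cells held 3.39% and 3.21% of epithelial-like cells in PSp mice and 2.29% and 2.51% in PCSp mice. With the same number of cells from each sub-cluster in every mouse, the cell cycle mean was -0.08 and no longer passed (adjusted p = 0.361), and in luminal-like cells alone it was -0.16 (adjusted p = 0.364). The list of p53 targets and senescence fell with a mean of -0.25, 12 of 15 lower and 0 when adjusted over the list alone (adjusted p = 0.0037; adjusted p = 0.748 with an estimated correlation). The cyclin-dependent kinase inhibitor gene Cdkn2b was at -0.41, Gdf15 at -0.74 and Phlda3 at -0.55. That call was lost without PSp mouse 2 (-0.19, adjusted p = 0.0549) and without PCSp mouse 1 (-0.25, adjusted p = 0.0564). The mitochondrially encoded genes, which serve the respiratory chain, fell with a mean of -0.34, 11 of 13 lower and 2 when adjusted over the list alone (adjusted p = 6.5e-08; adjusted p = 0.814 with an estimated correlation). Among them mt-Nd3 was at -0.98 ± 0.20, mt-Co3 at -0.55 and mt-Nd2 at -0.51. Without PSp mouse 2 the mean was -0.20 and mt-Co3 was -0.34. They took a median of 3.98% and 5.35% of the UMIs of epithelial-like cells in PSp mice and 3.46% and 3.35% in PCSp mice.

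The neuroendocrine markers rose with a mean of 1.13, 11 of 12 higher and 3 when adjusted over the list alone (adjusted p = 1.9e-09; adjusted p = 0.777 with an estimated correlation). The calcitonin gene Calca was at 2.15 ± 0.46, Resp18 at 1.72 ± 0.39 and the prohormone convertase gene Pcsk1 at 1.55 ± 0.33 (SE). These 3 genes were at low levels, with 15.9 CPM for Calca in PCSp mouse 1 as the highest value. The 7 and 10 neuroendocrine-like cells of the PSp mice and the 23 and 12 of the PCSp mice held 21.5%, 45.0%, 52.8% and 36.9% of these UMIs. The mean was -0.03 and did not pass with the same number of cells from each sub-cluster (adjusted p = 0.940), and 0.63 without PCSp mouse 1. The basal markers rose with a mean of 0.15, 11 of 16 higher and 2 when adjusted over the list alone (adjusted p = 0.0064; adjusted p = 0.881 with an estimated correlation). The plakin gene Dst was at 0.53 ± 0.10, the laminin gene Lamb3 at 0.38 ± 0.08 and the Notch ligand gene Jag2 at 0.52 ± 0.14. The basal mean turned to -0.10 without PSp mouse 2 (adjusted p = 0.385) and its call was lost without PCSp mouse 2 (0.06, adjusted p = 0.305). It was 0.47 without PSp mouse 1 and 0.23 without PCSp mouse 1. The luminal progenitor markers fell with a mean of -0.20, 10 of 10 lower and 1 when adjusted over the list alone (adjusted p = 0.0157; adjusted p = 0.814 with an estimated correlation). The surface antigen gene Ly6a was at -0.45, Wfdc2 at -0.44 and the keratin gene Krt7 at -0.24. The mean was -0.05 without PSp mouse 2 (adjusted p = 0.726) and -0.31 without PSp mouse 1. The list of secretory transcripts as free RNA fell with a mean of -0.86, 5 of 6 lower and 1 when adjusted over the list alone (adjusted p = 0.0360; adjusted p = 0.814 with an estimated correlation). Pate4 was at -2.91 ± 0.51 and the spermine-binding protein gene Sbp at -1.84 ± 1.72 (SE). The mean turned to 1.48 without PSp mouse 2 (adjusted p = 0.178) and was -1.79 without PCSp mouse 1. The 10 calls rest on a preset correlation between genes. None of them held with an estimated correlation or with fry, and the test also called 10 lists in each of the other 2 pairings of the 4 mice. An estimated correlation rests here on 2 residual degrees of freedom, and neither its power nor that of fry was simulated. Not passing with them therefore does not show that a list did not move.

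**Figure D3:**
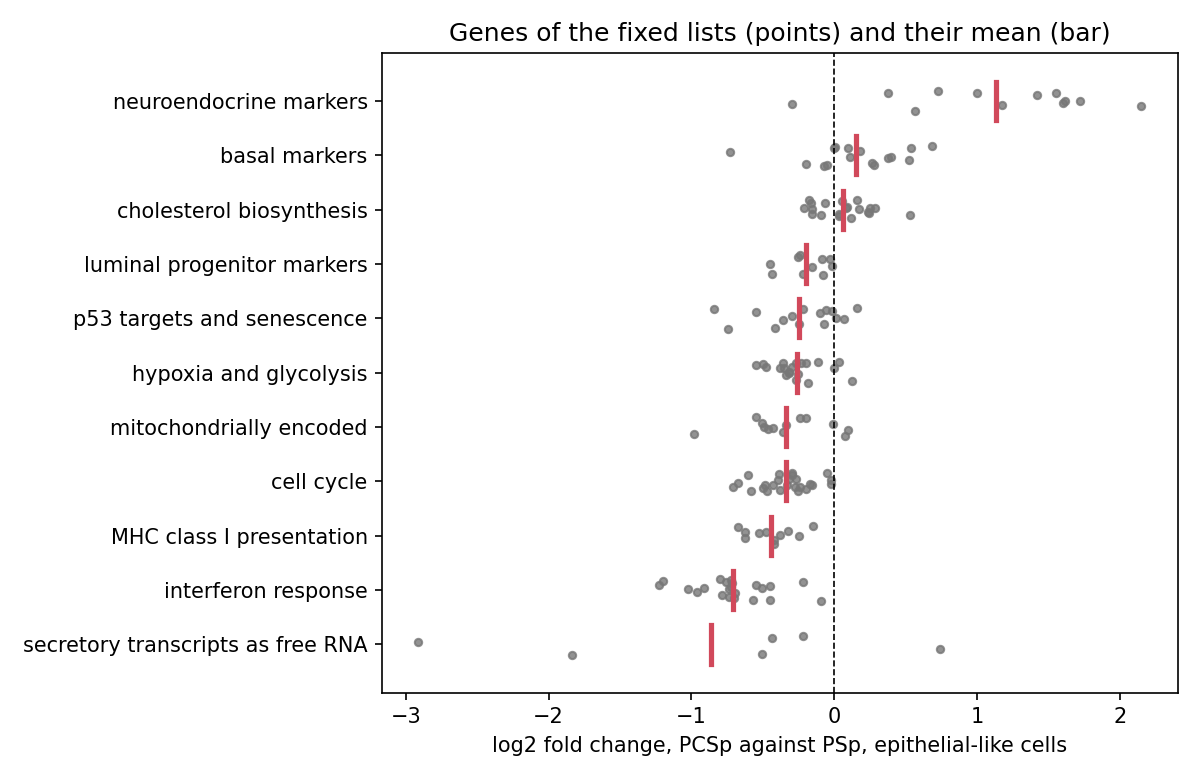
Each grey point is the log2 fold change of 1 gene in epithelial-like cells, PCSp against PSp mice (x axis), in the 10 lists that passed and the cholesterol biosynthesis list (y axis), and red bars are the means of each list. The interferon response genes all lie below 0, around a mean of -0.71, and the cholesterol genes lie around 0.06.

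Genes of cholesterol biosynthesis, the pathway the study is about, did not pass in the summed epithelium. Of the list, 13 of its 20 genes were higher in PCSp mice and 7 lower, with a mean of 0.06 and 0 genes when adjusted over the list alone (camera adjusted p = 0.211; adjusted p = 0.945 with an estimated correlation). The other 2 pairings of the mice gave means of -0.02 and -0.18. The enzyme genes Hmgcs1 and Msmo1 were at 0.29 ± 0.09 and 0.24 ± 0.10 (SE). The genes of SREBP2 control and cholesterol uptake had a mean of -0.09 (5 of 14 higher, adjusted p = 0.699), with the sterol carrier gene Stard4 at -0.65 and Lrp8 at -0.51. The cholesterol list did pass without PSp mouse 1 (0.17, adjusted p = 0.0135) and without PCSp mouse 1 (0.14, adjusted p = 0.0209), and turned to -0.03 and -0.02 without PSp mouse 2 and PCSp mouse 2. It also passed with the same number of cells from each sub-cluster in every mouse (0.12, adjusted p = 0.0071), a setting chosen after the values were seen. These 3 calls rest on the preset correlation, were not computed with an estimated one, and did not stand with it over all mice and cells (adjusted p = 0.945).

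None of the other 20 lists passed in the epithelium. Fatty acid synthesis genes had a mean of 0.02, cholesterol efflux and storage 0.10, steroid hormone synthesis -0.14 and oxidative phosphorylation -0.02. The unfolded protein and stress response had a mean of -0.11 and homologous recombination -0.05. The mesenchymal transition had a mean of 0.09, dissociation stress -0.09, NF-kB response genes 0.13, MHC class II genes 0.17 and the lineage factors of CHD1 loss studies 0.19. The adjusted p of these 11 lists ranged from 0.137 to 0.957. SPOP substrates had a mean of -0.03 and a median of 0.02 with the test pointing down (adjusted p = 0.765), with 1 gene lower when adjusted over the list alone: Daxx, which encodes a histone chaperone (-0.57 ± 0.08 SE). The PI3K feedback list had a mean of 0.01, a median of -0.04 and a test pointing up (adjusted p = 0.957), and the myeloid-recruiting cytokines a mean of 0.06, a median of -0.11 and a test pointing down (adjusted p = 0.834). Of the lists of other cell types, activated fibroblast and matrix had a mean of 0.17 and T and NK cell cytotoxicity 0.54 over 5 genes. T cell exhaustion had a mean of -0.01 with a median of 0.05 and the test pointing up. The inflammatory macrophage state had -0.03 with a median of 0.01 and the test pointing down, and the alternative macrophage state 0.06 with a median of 0.14 and the test pointing down (adjusted p from 0.154 to 0.957). In that last list Arg1, which encodes arginase, was lower when adjusted over the list alone (-0.999 ± 0.152 SE).

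Sums over the epithelial subclasses ask whether the same changes stood within luminal-like and within basal-like cells. In luminal-like cells, which include the luminal-progenitor-like ones, 17 of 12944 genes passed, 3 higher and 14 lower. Among them were Wdfy1 (log2 fold change 1.47 ± 0.14 SE, edgeR adjusted p = 0.0231), the antiviral TRIM genes Trim30d (-1.72 ± 0.16) and Trim12a (-1.40 ± 0.15), and Ocel1 (-1.19 ± 0.11). Wdfy1, Trim30d, Trim12a and Ocel1 moved the same way in all 6 classes tested, also where the Cre is not active. Hsd11b2, which encodes an enzyme that inactivates glucocorticoids, fell by 1.10 ± 0.13 and Oas2 fell by 1.04 ± 0.12. In basal-like cells 4 of 13855 genes passed, 3 higher and 1 lower. Wdfy1 rose by 1.63 ± 0.13 (adjusted p = 0.0401) and the interferon-induced Slfn2 fell by 1.24 ± 0.08 (adjusted p = 0.0152), and the others were a predicted gene model and the haemoglobin gene Hba-a1 at 2.87 CPM, named here after its values were seen. DESeq2 called 100 and 257 genes in the 2 subclasses. Leaving out PSp mouse 1, PSp mouse 2, PCSp mouse 1 or PCSp mouse 2 gave 78, 71, 38 and 85 genes in luminal-like cells and 0, 16, 53 and 3 in basal-like cells. With doublets kept the counts were 2 and 0. Without sub-cluster 7 the luminal-like count was 20, and the means of cholesterol biosynthesis in luminal-like cells and interferon response in luminal-like cells were 0.19 and -0.42, both past the threshold at the preset correlation. With sub-cluster 7 kept, neither passed with an estimated correlation (adjusted p = 0.849 for both), which was not computed without it. Sub-cluster 10, led by Upk1b, was kept either way.

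Genes of cholesterol biosynthesis rose in luminal-like cells, 14 of 20 higher with a mean of 0.13 and 1 when adjusted over the list alone (camera adjusted p = 0.0362; adjusted p = 0.849 with an estimated correlation). The other 2 pairings of the mice, which do not split them by genotype, moved the luminal-like mean nearly as far, to -0.11 and -0.06. The rise was not shared by the luminal-like sub-cluster 1, where the mean was -0.08 with 14 of 20 lower (adjusted p = 0.609), while in the luminal-progenitor-like sub-cluster 10 it was 0.46 (adjusted p = 3.9e-09; adjusted p = 0.667 with an estimated correlation). In the summed basal-like cells the genes fell, 16 of 20 lower with a mean of -0.27 and 0 when adjusted over the list alone (adjusted p = 0.0040; adjusted p = 0.660 with an estimated correlation). A fall of nearly the same size, -0.26, arose in 1 of the other pairings of the mice, and the other gave -0.11. With the same number of cells from each sub-cluster the basal-like mean was -0.0692 and did not pass, and within the basal-like sub-clusters 0, 3 and 5 it was 0.03, -0.01 and -0.22, none of which passed. The difference between the subclasses was 0.38 (adjusted p = 1.2e-05; adjusted p = 0.713 with an estimated correlation). The luminal-like call was lost without PSp mouse 2 (0.04, adjusted p = 0.674) and PCSp mouse 1 (0.11, adjusted p = 0.210) and the mean was 0.21 without PSp mouse 1. The basal-like call was lost without PSp mouse 1 (-0.09, adjusted p = 0.379) and PCSp mouse 1 (-0.19, adjusted p = 0.222) and the mean was -0.41 without PSp mouse 2. Genes of the interferon response fell in both, with means of -0.44 (18 of 22 lower) and -0.87 (21 of 22 lower). Of these, 14 and 18 were lower when adjusted over the list alone (adjusted p = 3.9e-21 and 5.1e-39; adjusted p = 0.849 and 0.492 with an estimated correlation). MHC class I, hypoxia and glycolysis and mitochondrially encoded genes fell in both subclasses, with means of -0.29, -0.20 and -0.35 in luminal-like and -0.57, -0.28 and -0.42 in basal-like cells. Their adjusted p ranged from 1.2e-11 to 3.4e-04 in luminal-like and from 7.2e-14 to 8.4e-09 in basal-like cells, and was 0.849 and 0.492 for each with an estimated correlation. In luminal-like cells the list of MHC class II presentation rose (0.56, adjusted p = 1.5e-05; adjusted p = 0.849 with an estimated correlation). In basal-like cells the genes of SREBP2 control (-0.28), the cell cycle (-0.45), p53 and senescence (-0.41) and luminal progenitors (-0.24) fell, and those of the mesenchymal transition (0.25) and basal markers (0.20) rose. Adjusted p of these 6 lists ranged from 4.6e-10 for the cell cycle to 0.0122 for SREBP2 control and cholesterol uptake, and from 0.492 to 0.618 with an estimated correlation. Without PSp mouse 2 the basal-like cell cycle mean was -0.22. Without PCSp mouse 2 the luminal-like MHC class II mean was 0.85 and the basal-like luminal progenitor markers were at -0.41, against -0.38 without PSp mouse 1. The mesenchymal transition mean in basal-like cells was 0.14 without PSp mouse 1 and turned to -0.08, -0.05 and -0.07 without PSp mouse 2, PCSp mouse 1 and PCSp mouse 2. Without PCSp mouse 1 the basal-like calls of SREBP2 control and cholesterol uptake (-0.27), luminal progenitor markers (-0.09) and basal markers (0.09) and the luminal-like call of MHC class II presentation (0.25) were lost. The calls of SREBP2 control (-0.09) and basal markers (0.16) in basal-like cells were lost without PSp mouse 1 as well. Those of luminal progenitor markers in basal-like cells (-0.07) and of hypoxia and glycolysis in luminal-like cells (-0.16) were lost without PSp mouse 2.

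**Figure D4:**
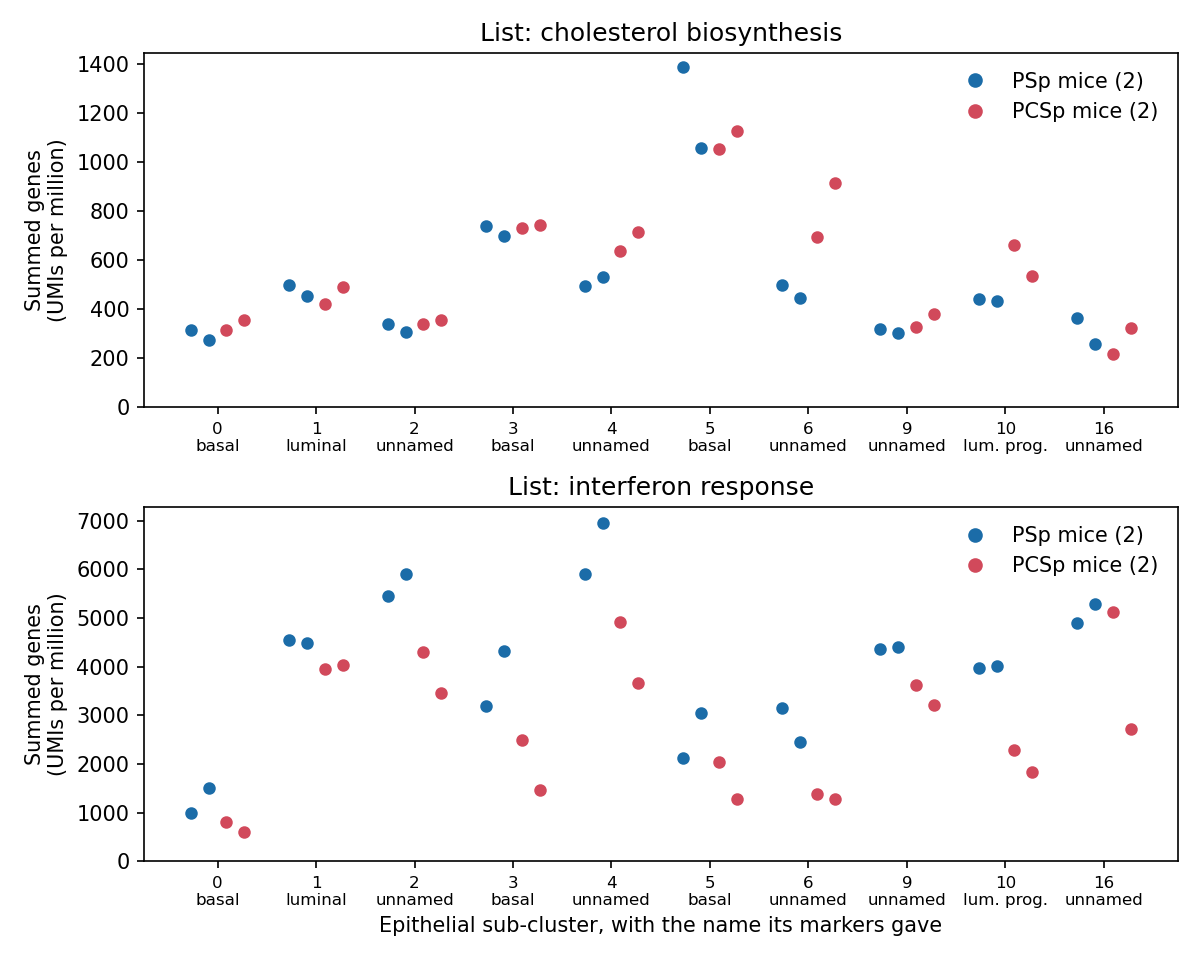
Each point is the summed level of a gene list (CPM, y axis) in the cells of 1 epithelial sub-cluster (x axis) from 1 mouse, for cholesterol biosynthesis (top) and the interferon response (bottom), with PSp mice in blue and PCSp mice in red. In sub-cluster 6 the cholesterol genes summed to 497 and 445 in PSp mice and to 694 and 914 in PCSp mice.

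The other cell classes show what changed in cells outside the reach of the epithelial Cre. In macrophages and monocytes 8 of 10016 genes passed, 4 higher and 4 lower. Mfge8 (chromosome 7), whose product bridges dying cells and phagocytes, rose from 21.3 and 21.0 CPM in PSp mice to 289 and 363 in PCSp mice, a log2 fold change of 3.94 ± 0.17 (SE, edgeR adjusted p = 5.0e-05). The gene of the epidermal growth factor receptor ligand amphiregulin, Areg, rose by 1.68 ± 0.19 (adjusted p = 0.0246), and the interleukin-2 receptor gene Il2ra fell by 1.70 ± 0.18 (adjusted p = 0.0177) and the haem-binding protein gene Hebp1 fell by 1.41 ± 0.17 (adjusted p = 0.0366). Mfge8 lay at 17.1 times the level that epithelial RNA, at the share its markers reach there, could leave in these cells, and Areg at 4.35 times that level. The alternative and lipid-associated macrophage state rose with a mean of 0.44, 12 of 16 higher and 1 when adjusted over the list alone. The cell cycle list rose as well (0.21), while interferon response (-0.22), T cell exhaustion (-0.45), dissociation stress (-0.19) and mitochondrially encoded genes (-0.44) fell. Camera adjusted p ranged from 1.3e-11 to 0.0226, with no adjusted p under 0.845 with an estimated correlation. The test called 6 lists, against 6 and 9 in the other 2 pairings of the mice, whose interferon response means were -0.36 and -0.08. The cluster led by Retnla, Clec10a and Mrc1 held 21.5% and 15.5% of these cells in PSp mice and 25.5% and 33.3% in PCSp mice. With the same number of cells from each cluster in every mouse the alternative state was 0.45 and still passed. Mfge8 then rose by 3.98 and passed, while Areg (1.30), Il2ra (-1.40) and Hebp1 (-1.03) no longer did. The macrophage alternative and lipid-associated state was 0.11 without PSp mouse 2 (adjusted p = 0.419), 0.01 without PCSp mouse 2 and 1.22 without PSp mouse 1, and T cell exhaustion was 0.16 without PSp mouse 2. The cell cycle list turned to -0.19 and passed in that direction without PSp mouse 1 (adjusted p = 0.0370), and was 0.88 without PSp mouse 2 and 0.16 without PCSp mouse 2 (adjusted p = 0.0646). The interferon mean was -0.003 without PSp mouse 1, -0.35 without PSp mouse 2, -0.37 without PCSp mouse 1 and -0.10 without PCSp mouse 2. T cell exhaustion was -0.79 without PSp mouse 1. Dissociation stress was -0.11 without PSp mouse 2, -0.35 without PCSp mouse 1 and -0.06 without PCSp mouse 2. The gene count was 58, 45, 51 and 17 without each mouse in turn, PSp mice first, 24 by DESeq2 and 4 with doublets kept.

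In T and NK cells 37 of 7830 genes passed, 9 higher and 28 lower. The NK receptor gene Klra5 fell from 98.8 and 87.1 to 7.75 and 9.15 CPM (-3.47 ± 0.24 SE, edgeR adjusted p = 4.1e-06). Ifi44 fell by 2.41 ± 0.39, the osteopontin gene Spp1 by 1.82 ± 0.21, Lat2 by 1.57 ± 0.27 and Cxcl10, which encodes a chemokine that draws T cells, by 1.56 ± 0.14, with adjusted p from 9.0e-05 to 0.0123. Reg3b (2.47 ± 0.36) and Reg3g (1.13 ± 0.16), which encode secreted antimicrobial lectins, rose. So did the antibody light chain gene Igkc (2.06 ± 0.30), the histone gene Hist1h2ae (1.04 ± 0.20) and Rgcc (0.83 ± 0.13). Reg3b, Reg3g and Igkc were higher in PCSp mice in all 6 classes tested, epithelium included. In T and NK cells Reg3b and Reg3g lay at 1.19 and 1.08 times the level that epithelial RNA could leave there. Igkc lay at 0.067 times the level that B and plasma cell RNA could leave. The rises of Reg3b, Reg3g and Igkc in T and NK cells therefore cannot be told apart from free RNA. Hist1h2ae and Rgcc lay at 98.5 and 14.2 times the level that any other class could leave. All 21 interferon response genes tested were lower, with a mean of -0.72. Of these, 4 were called over all genes and 13 when adjusted over the list alone (camera adjusted p = 3.1e-22; adjusted p = 0.593 with an estimated correlation). The mean was -0.42 without PSp mouse 2 and -0.69 with the same number of cells from each cluster in every mouse. Hypoxia and glycolysis (-0.29) and mitochondrially encoded genes (-0.35) fell too, as did the mesenchymal transition list (-0.25 over 5 genes), whose call was lost without any 1 of the 4 mice (0.36, 0.06, 0.18 and 0.08, PSp mice first). Camera adjusted p of these 3 lists ranged from 1.1e-14 to 0.0055, and was 0.593 for each with an estimated correlation. The test called 4 lists, against 4 and 5 in the other pairings of the mice. The gene count was 131, 106, 90 and 87 without each mouse in turn, 30 by DESeq2 and 5 with doublets kept.

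In neutrophils 8 of 9134 genes passed, 2 higher and 6 lower, of which 4 were predicted gene models. Trim12a fell by 1.41 ± 0.16 (SE, edgeR adjusted p = 0.0080), the interferon-induced helicase gene Helz2 by 1.13 ± 0.15 (adjusted p = 0.0191) and Trim30d by 1.11 ± 0.15 (adjusted p = 0.0218). Trim12a and Trim30d were lower in PCSp mice in all 6 classes tested. All 22 interferon response genes were lower, with a mean of -0.53 and 9 when adjusted over the list alone (camera adjusted p = 3.0e-13; adjusted p = 0.701 with an estimated correlation). The mean was -0.33 without PSp mouse 2, -0.81 without PCSp mouse 1 and -0.30 without PCSp mouse 2. The neutrophil cluster led by the interferon-induced genes Rsad2 and Ifit2 held 27.8% and 31.8% of neutrophils in PSp mice and 23.6% and 16.0% in PCSp mice. With the same number of cells from each cluster the mean was -0.10, 10 of 22 lower, and did not pass (adjusted p = 0.805). That cluster is set apart by interferon genes themselves, so the setting removes part of any change in them. Dissociation stress (-0.26), hypoxia and glycolysis (-0.19) and mitochondrially encoded genes (-0.31) fell, and matrix genes (0.88 over 9 genes) and basal markers (0.38 over 8 genes), which belong to other cell types, rose. Camera adjusted p of these 5 lists ranged from 0.0010 to 0.0076, and none was under 0.701 with an estimated correlation. The test called 6 lists, against 1 and 7 in the other pairings of the mice. Each of these 5 lists lost its call when some mouse was left out. Without PSp mouse 1 dissociation stress was -0.10 and hypoxia and glycolysis -0.13. Mitochondrially encoded genes and basal markers were both 0.02 without PSp mouse 2, and -0.14 and 0.11 without PCSp mouse 2. Matrix genes were 0.38 without PCSp mouse 2. Other moves by over 1.5 times were basal markers at 0.60 and mitochondrially encoded genes at -0.59 without PSp mouse 1, basal markers at 0.14 and mitochondrially encoded genes at -0.51 without PCSp mouse 1, and dissociation stress at -0.41 without PSp mouse 2. Epithelial marker RNA in neutrophils lay at a median of 4.77% and 5.33% of its epithelial level in PSp mice and 6.20% and 6.58% in PCSp mice. The gene count was 7, 50, 408 and 106 without each mouse in turn, 17 by DESeq2 and 15 with doublets kept.

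No gene passed in fibroblasts or endothelial cells by edgeR. The counts were 0 of 12117 with 459 at an unadjusted p under 0.05, and 0 of 9162 with 593, against 4 and 6 by DESeq2. Leaving out each mouse in turn gave 91, 12, 131 and 9 genes in fibroblasts and 140, 90, 61 and 14 in endothelial cells. In fibroblasts the matrix genes (0.57, 15 of 16 higher), MHC class II genes (0.46) and the alternative macrophage list (0.43) rose, and interferon response genes (-0.24, 17 of 22 lower) and mitochondrially encoded genes (-0.39) fell. Their camera adjusted p ranged from 3.45e-10 to 0.0211, with no adjusted p under 0.788 with an estimated correlation. The other pairings of the mice called 3 and 7 lists in fibroblasts, against 5, and gave interferon response means of -0.30 and -0.17. With the same number of cells from each cluster the mean of the macrophage alternative and lipid-associated state was 0.06 and did not pass (adjusted p = 0.629), and matrix genes were at 0.27. The matrix mean was 0.12 without PCSp mouse 2 (adjusted p = 0.0846), 0.90 without PSp mouse 1 and 0.34 without PSp mouse 2, and that of MHC class II presentation 0.23 without PSp mouse 2 (adjusted p = 0.0582), 0.76 without PSp mouse 1 and 0.26 without PCSp mouse 2. The interferon mean was -0.44 without PSp mouse 2, and the macrophage list 0.22 without PCSp mouse 2. Without PSp mouse 1 the interferon mean was 0.04 and the macrophage list 0.49 with an adjusted p of 0.122. In endothelial cells interferon response genes rose (0.25, 17 of 22 higher, adjusted p = 0.0055; adjusted p = 0.684 with an estimated correlation), a call that was lost without PSp mouse 2 (0.13) and without PCSp mouse 1 (-0.02), while the mean was 0.46 without PSp mouse 1 and 0.40 without PCSp mouse 2. The other pairings gave -0.39 and 0.10 for this list and called 7 and 4 lists, against 7. Matrix genes (0.50), dissociation stress (0.21), myeloid-recruiting cytokines (0.30), basal markers (1.64) and luminal progenitor markers (0.55) rose and mitochondrially encoded genes fell (-0.40), with no adjusted p under 0.684 with an estimated correlation. Without PCSp mouse 1 the calls of basal markers (0.45), luminal progenitor markers (0.33) and dissociation stress (0.14) were lost, and without PCSp mouse 2 those of matrix genes (0.03) and cytokines (-0.34). Without PSp mouse 2 luminal progenitor markers, cytokines and matrix genes were 0.60, 0.38 and 0.42, none of which passed, and cytokines were 0.74 without PCSp mouse 1. The endothelial cluster led by Ccl21a, Lyve1 and Prox1 held 8.50% and 15.2% of the class in PSp mice and 28.0% and 21.4% in PCSp mice. With the same number of cells from each cluster the interferon response (0.20, adjusted p = 0.102) and luminal progenitor markers (0.30, adjusted p = 0.0830) no longer passed. The gene counts were then 3 in fibroblasts and 1 in endothelial cells. Epithelial marker RNA in endothelial cells lay at a median of 1.67% and 2.15% of its epithelial level in PSp mice and 3.79% and 2.77% in PCSp mice. The cholesterol list passed in none of the 5 other classes.

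The difference of the genotype effect between the epithelium and each other class was tested with the mouse as a term. It passed for 78 genes against endothelial cells, 3 against fibroblasts, 8 against macrophages and monocytes, 10 against neutrophils and 62 against T and NK cells. Mfge8 was among them (epithelial minus macrophage difference -3.99, adjusted p = 7.3e-07), as were Cxcl10 and Spp1 against T and NK cells (1.08 and 2.31, adjusted p = 2.5e-10 and 1.9e-11). With no filter on low counts the counts were 125, 135, 156, 102 and 57, with doublets kept 8, 3, 7, 93 and 56, and with the other normalization the count against macrophages and monocytes was 2 and that against fibroblasts 2.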

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

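All tests of explanations in this part were chosen after the result was seen, except that of free RNA from other cell classes for the interferon genes, whose outcome was set down before it was computed; the genes named as shared between classes were chosen after their values were seen.

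Interferon response genes were lower in the PCSp epithelium, with a mean log2 fold change of -0.71. After thinning every mouse to the same cells and UMIs the mean was -0.715. Such thinning keeps the expected share of each gene. It therefore cannot decide whether depth per cell affected which barcodes were kept or how they were named. Another mix of the sub-clusters is excluded as the whole cause, since the mean was -0.540 with the same number of cells from each sub-cluster. Shifts of cells within a sub-cluster are not covered by this setting. Sub-cluster 8, led by the interferon-induced genes Ifit2 and Rsad2, held 1.75% and 2.01% of epithelial-like cells in PSp mice. In PCSp mice it held 0.838% and 0.716%. The setting therefore also removes part of any change in these genes. Free RNA from other classes is excluded too: relative to the class with most of each gene, the median level in epithelial cells was 327 times that of this class's markers. Loss of Chd1 in the epithelium stays open as an untested biological explanation, as does any other difference between these 2 pairs of mice. T and NK cells, where the Cre is not active, showed lower interferon genes as well (-0.72, and -0.69 with the same number of cells from each cluster). So did neutrophils, whose mean of -0.53 was -0.10 in that setting, fibroblasts (-0.24) and macrophages and monocytes (-0.22). Endothelial cells showed higher ones (0.25). In fibroblasts, macrophages and monocytes and endothelial cells another pairing of the mice gave means of larger size (-0.30, -0.36 and -0.39). In T and NK cells and neutrophils no other pairing went beyond 0.38.

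Cholesterol biosynthesis genes stood out by a difference of 0.38 between luminal-like and basal-like cells (adjusted p = 1.2e-05), which was 0.24 with the same number of cells from each sub-cluster (adjusted p = 0.0136) and did not pass with an estimated correlation in either (adjusted p = 0.713 and 0.675). By sub-cluster, the list was higher in PCSp mice in sub-cluster 4 (0.36, 20 of 20 genes), 6 (0.67, 19 of 20) and the luminal-progenitor-like 10 (0.46, 17 of 20), with camera adjusted p of 7.3e-10, 1.6e-21 and 3.9e-09 and adjusted p = 0.524, 0.635 and 0.667 with an estimated correlation; sub-clusters 4 and 6 took no subclass name, and it did not pass in the other 7, with means of -0.08 in the luminal-like 1, 0.08, 0.15 and -0.21 in the unnamed 2, 9 and 16 and 0.03, -0.01 and -0.22 in the basal-like 0, 3 and 5. The lower level in the basal-like sum may come from its makeup, since its mean moved from -0.27 to -0.0692 with the same number of cells from each sub-cluster, and a pairing of the mice that does not split them by genotype gave -0.26. Whether free RNA from these 3 sub-clusters spread cannot be told from the basal-like sub-clusters 0 and 3, whose higher mean was 0.0281. Their own level of the list is high, and free RNA at 6.58% of its source could raise it by 0.103 at most. The mean rise in the 3 sub-clusters was 0.498, and free RNA from them could not by itself give a rise in its own source. The rise within the 3 sub-clusters is a hypothesis for an effect of Chd1 loss that was found and tested on the same cells.

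Across all 6 classes, 38 of 6376 genes tested in each moved one way with an unadjusted p under 0.05 in at least 4 of them, 18 higher and 20 lower, against 0 and 5 in the other pairings of the mice; 8 are mitochondrially encoded. Free RNA from epithelial cells is excluded for 17 of the nuclear genes. These lay above 5 times the level that epithelial markers reach in every other class. Among them are Trim34a, Trim12a and Trim30d (chromosome 7, 104244457 to 104507849, GRCm38), Ocel1, Ddx60 and Wdfy1. The antibody gene Igkc is also among the 17, but for it the source would be plasma cells, which this test does not cover. In T and NK cells Igkc lay at 41.6 CPM, and B and plasma cell RNA could leave 621 CPM there. Free RNA of those cells is therefore not excluded for Igkc. The other 13 nuclear genes lay at no more than 5 times that level in some other class, though not necessarily in each. For them this level cannot tell free epithelial RNA apart from a change shared by all classes. Reg3b and Reg3g are such genes. Chromosome segments of another mouse strain that were inherited with the genotype could give such genes, and they cannot be told apart from other causes: with overlapping genes counted as 1 and 1 gene per family, 2 of 14 genes had a neighbour within 5 Mb against a median of 0 in random draws (permutation p = 0.419), while with all members of a family kept 5 of 16 had one against 0 (permutation p = 0.0264), and 0 lay within 20 Mb of Chd1. Loss of Chd1 in the epithelium as the source of changes in all classes was not tested.

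The remaining results stood out because the genotype effect differed between classes, by a test of the difference. For the interferon list the epithelial change minus the endothelial one was -0.92 (adjusted p = 3.0e-13), minus that of fibroblasts -0.51 (adjusted p = 5.2e-06) and minus that of macrophages and monocytes -0.49 (adjusted p = 2.3e-06). Against neutrophils the difference was -0.17 (adjusted p = 0.0072). Against T and NK cells it was -0.38 and did not pass the threshold (adjusted p = 0.407). The means from the separate test of each class were close there, at -0.71 in the epithelium and -0.72 in T and NK cells. The luminal-like mean was higher than the basal-like one by 0.43 (adjusted p = 3.9e-14), and no adjusted p of these differences was under 0.712 with an estimated correlation. The test of the difference passed for 78 genes against endothelial cells, 3 against fibroblasts, 8 against macrophages and monocytes, 10 against neutrophils and 62 against T and NK cells. For Chd1 the difference was -0.83 against neutrophils and -1.01 against T and NK cells.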

How the results depend on the processing

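The settings of equal sub-cluster mix, without low-UMI and immune-led sub-clusters, without neuroendocrine-like cells, without the uroplakin-led sub-cluster and of equal cluster mix, and all alternatives for lists outside the epithelium, were chosen only after the results were seen. No paired analysis was possible because the labels number the mice of each genotype in order only and pair no PSp mouse with a PCSp mouse. When a mouse was left out, the lone mouse of its genotype was assumed to vary like the pair of the other. Over all alternatives, named genes kept their direction and their side of the threshold in 1074 cases, gained a call in 41, lost one in 35 and turned in 11. Lists did so in 187, 4, 48 and 8 cases, shares kept both in 91 and turned in 14, and counts stayed within 1.5 times in 74 and moved in 61. The cause of the changes listed here was not tested, except that no filter on low counts adds genes to the test and that a mouse left out leaves fewer samples. The low depth of PCSp mouse 2 and the 2 mice per genotype limit what a share or gene test can show.

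Gene counts moved by more than 1.5 times under several settings, in the order epithelial, fibroblast, neutrophil, macrophage and monocyte, T and NK, endothelial, luminal-like and basal-like. With no filter on low counts they were 29, 152, 194, 54, 145, 179, 496 and 811, and the total of differences between classes went from 161 to 575. DESeq2 gave 181, 4, 17, 24, 30, 6, 100 and 257. Leaving out 1 mouse gave 0 to 2, 9 to 131, 7 to 408, 17 to 58, 87 to 131, 14 to 140, 38 to 85 and 0 to 53. With doublets kept the counts were 15 in neutrophils, 4 in macrophages and monocytes, 5 in T and NK cells, 2 in luminal-like and 0 in basal-like cells. With DESeq2's size factors the basal-like count was 27. In luminal-like cells only the epithelial count was 17, and with an equal sub-cluster mix the epithelial, luminal-like and basal-like counts were 17, 66 and 9. With an equal cluster mix the fibroblast count was 3 and the endothelial count 1.

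The number of lists called was 10 in the epithelium and 28 in the other classes, and 0 and 0 with an estimated correlation and 0 and 0 with fry; it was 6 in luminal-like cells only. The mean log2 fold changes do not depend on the set test, so the interferon values of -0.71, -0.44 and -0.87 (epithelial, luminal-like, basal-like) and the cholesterol values of 0.13 and -0.27 (luminal-like, basal-like) stayed and lost their calls. The interferon list in the epithelium kept its direction and its call under every other setting, from -0.90 to -0.44. The mean of cholesterol biosynthesis in epithelial cells, 0.06, passed at 0.13 in luminal-like cells only and at 0.12 with an equal sub-cluster mix, was -0.00689 with all cells summed, and ranged from -0.0313 to 0.17 with a mouse left out. The luminal-like mean ranged from 0.0445 to 0.21 and the basal-like mean from -0.41 to -0.0922, and the latter was -0.0692 with an equal sub-cluster mix.

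The mean of basal markers in epithelial cells turned to -0.0471 in luminal-like cells only and -0.0792 with an equal sub-cluster mix and ranged from -0.10 to 0.47 with a mouse left out. The mean of neuroendocrine markers in epithelial cells turned to -0.0272 with an equal sub-cluster mix and was 0.55 without a call by cells' own markers, and secretory transcripts ranged from -1.79 to 1.48 with a mouse left out. Log2 ratios of shares also turned, none of them past the threshold before or after. The neutrophil ratio was -0.10 as a share of non-epithelial cells, -1.07 with the stricter filter and from -0.27 to 0.40 with a mouse left out. The endothelial ratio was -0.13 as a share of non-epithelial cells, -0.0296 with all barcodes and -0.0300 by cells' own markers, and from -0.30 to 0.35. The basal-like ratio was -0.12 at Leiden resolution 2 and from -0.0788 to 0.53, the luminal-like ratio was 0.0558 by cells' own markers and from -1.17 to 1.03, and the luminal-progenitor-like ratio was from -0.88 to 1.07. Other ratios kept their direction and moved by over 1.5 times. The epithelial ratio was -0.0644 at Leiden resolution 2 and -0.11 with the stricter filter, and that of macrophages and monocytes 0.69 with the stricter filter and 0.13 as a share of non-epithelial cells. As such a share, fibroblasts were at 0.0998 and T and NK cells at 0.12. As shares of all cells they were at 0.10 and 0.0764 without PCSp mouse 1, and at 0.47 and 0.52 at most with another mouse left out. The neuroendocrine-like ratio, 0.76, ranged from 0.28 to 1.11 with a mouse left out. The luminal-like ratio was -0.83 with doublets kept, -0.18 with the stricter filter, -0.79 at Leiden resolution 0.5 and -0.85 at resolution 2, and the luminal-progenitor-like ratio -0.0117 with all barcodes, -0.42 at resolution 0.5 and -0.06 at resolution 2.

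Of the named genes in the epithelium, none of which passed there, Resp18 turned to -0.62 by cells' own markers. In luminal-like cells only, Lamb3 was -0.44 and Cdkn2b was 0.0545. With all cells summed Mrc1, of the alternative macrophage list (-0.37 in the epithelium), was 0.35. The value of Srebf2 in epithelial cells was 0.0249 with equal cells and depth, 0.00217 with an equal sub-cluster mix, 0.00657 without low-UMI and immune-led sub-clusters and from -0.13 to 0.13 with a mouse left out. Sbp was 1.31 with an equal sub-cluster mix and from -2.83 to 3.96 with a mouse left out.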

Other observations

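Every test in this part was chosen after the data were seen, and the genes named here were too, unless they are named in the report. Sub-clusters with at least 50 cells in every mouse showed lower interferon response genes in PCSp mice in 10 of 10 cases, with mean log2 fold changes from -0.12 in luminal-like sub-cluster 1 to -1.17 in basal-like sub-cluster 3, and camera adjusted p up to 0.0224 (adjusted p from 0.195 with an estimated correlation). The summed level of these genes in basal-like sub-cluster 3 was 3192 and 4314 CPM in PSp mice and 2497 and 1472 in PCSp mice. In sub-cluster 6 it was 3145 and 2441 in PSp mice and 1388 and 1279 in PCSp mice.

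In T and NK cells Fcer1g and Tyrobp, which encode adaptors of activating receptors on NK and myeloid cells, fell by 1.05 (edgeR adjusted p = 0.0035) and 0.85 (adjusted p = 0.0057). The granzyme gene Gzma fell by 0.83 (adjusted p = 0.0093), while Pdcd1, which encodes the inhibitory receptor PD-1, rose by 0.63 (adjusted p = 0.0318). The class pools T and NK cells, and its cluster led by Nkg7 and Gzma also has Cd8b1 and Cd8a among its leading genes. For these genes and Klra5, a change within T and NK cells cannot be told apart from a shift in their mix. Fcer1g was at 622 CPM in these cells, 93.7 times the level that macrophage RNA could leave there at the share macrophage markers reach, and Tyrobp at 430 CPM, 56.5 times that of neutrophil RNA. In the epithelium Fcer1g, Tyrobp and Gzma were at 6.89, 7.85 and 0.586 CPM, which was 1.57, 1.74 and 0.262 times such a level, so their differences between the classes, among the 62 called, are not read as effects in the epithelium. The fixed list of T and NK cell cytotoxicity, which holds Gzma, did not pass within T and NK cells (mean -0.11, 7 of 12 higher, adjusted p = 0.278). At the preset correlation it passed with the same number of cells from each cluster (-0.32, adjusted p = 1.8e-06) and without PSp mouse 1 (-0.19, adjusted p = 0.0099). Against endothelial cells, differences included the interferon-induced Ifit1 (-1.46, adjusted p = 1.0e-04) and Rsad2 (-1.45, adjusted p = 3.7e-04) and the keratin gene Krt17 (-4.24, adjusted p = 2.8e-04), a gene of epithelial cells. In macrophages and monocytes Apold1 fell by 4.83 and the calcium channel gene Cacna1a by 4.34, both under 20 CPM on average.

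The mitochondrially encoded mt-Nd3 had a mean log2 fold change of -0.96 over the 6 classes with an SD of 0.03 between them, and mt-Co2 had -0.42 with an SD of 0.03. With 2 mice per genotype, only 3 splits of the mice into pairs exist, too few for a share under 0.05: the genotype split gave 1266 epithelial genes at an unadjusted p under 0.05 and the highest other split gave 1375, and it gave 37 genes past the threshold in T and NK cells, 17 in luminal-like cells, 8 in neutrophils, 8 in macrophages and monocytes and 4 in basal-like cells, against 2, 1, 1, 0 and 1 as the highest of the others. In the 3 other classes another split gave more: 0 in the epithelium against 1, 0 in endothelial cells against 3 and 0 in fibroblasts against 7, where 459 genes had an unadjusted p under 0.05 against 1246. The cause of the fibroblast values was not tested.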
